A study of Picea abies with 60 samples.

How the data were processed

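CG methylation was measured in vegetative terminal buds of Norway spruce by bisulfite conversion (EZ DNA Methylation-Gold), capture of targeted genes (SeqCap Epi) and paired-end sequencing. The deposited files of the authors hold counts of methylated and unmethylated reads per cytosine, without normalization. Per the submitters' processing notes Trimmomatic 0.36, Bismark 0.17.0 and Bowtie made these files, with no parameters stated. Only cytosines with at least 10 reads are listed, and nearly all are in CG context. The authors' annotation of the targeted genes gives sequences, Pfam descriptions, Arabidopsis homologs, the reason a gene was chosen, and an average coverage as a signal, whose computation is not stated and which was not used here. Annotated sequences were at hand for 2214 targets, and 2114 targets could be placed with each measured position on a CG of the sequence.

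Groups were taken from the labels, as 20 combinations of 2 treatments and 10 dates with 3 libraries each. A library was usable if it listed at least 10% of the median number of cytosines, which left 59 of 60. Common sites had at least 10 reads in at least 80% of usable libraries. Counts were summed per gene over both strands, and a gene was tested with at least 5 sites and at least 50 methylated and 50 unmethylated reads. The 6 title numbers served as replicates for temperature, since the titles repeat them over the dates, and are called A to C at 18 and D to F at 28 degrees, in ascending order of the number. Intervals cover counting error only, because reads carry no molecular identifiers.

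Gene and site differences were tested by edgeR 4.0.16 quasi-likelihood fits on methylated and unmethylated counts in R 4.3.3, with Benjamini-Hochberg adjustment and an FDR threshold of 0.05. For temperature, counts were summed over dates, giving 3 sums at 18 and 3 at 28 degrees. Season, date, interaction and temperature at single dates came from a fit with 1 mean per treatment and date. Season set 5 November, 19 December, 18 February and 20 March against 5 June, 13 June, 18 June and 30 July. Single cytosines needed at least 10 methylated and 10 unmethylated reads over the 6 sums. Levels over all sites were compared by exact permutation tests or by permutation tests with 100000 resamples in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. limma 3.58.1 on log2 ratios with a pseudocount of 1 served as the other tool.

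The groups, tests, season dates, gene lists, rule for naming genes and most alternatives were set before the data were examined. By that rule, temperature and season genes past the threshold were ranked by their difference in points, and the 5 largest in each direction were named. Temperature genes also had to have no overlap between numbers, and season genes had to move the same way in all 6. For dates the 3 smallest p were named, for single dates the 5 smallest past the threshold, and where nothing passed the 3 smallest. For gene lists the rule allowed up to 4 members. After values were seen this was reduced to the 2 with the largest difference, or 3 for cytokinin. The directions per number without 5 June and the B library of 20 March, and the gaps at single dates without each library, were also added after values were seen. The lists were matched to the description columns and covered DNA methylation, small RNA, chromatin, photoreceptors and clock, flowering, cold and dehydration, heat shock and chaperones, abscisic acid, gibberellin, auxin, cytokinin, ethylene, cell cycle, transposons, cell wall, ribosomal proteins and defence. Comparisons of levels between gene groups, the private sites and the coverage ratio were chosen after the data were seen.

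Alternatives covered the coverage minimum, filters, limma, centring, unweighted means of site levels, libraries as replicates, index sets, a replicate block, dates and libraries left out, each number left out, and the coverage ratio as a covariate. The coverage ratio used sites covered in all 59 libraries, 6693 above 90% and 33119 below 2%. The fits were tested on simulated data, in which every gene or site had the same noise, the median residual SD. Shifts shared by a date or a number were not simulated, except where measured shifts are stated. Recovery in the real data may therefore be lower. With 100 genes changed, a log2 odds ratio of 1 was recovered for 100% of genes by temperature, 99% by season, 62% by interaction and 25% at a single date. At single cytosines a value of 2 was recovered for 2% and a value of 5 for 91%. With the libraries' measured shifts and no gene changed, season gave 275 false calls, and 0 with the covariate. With these shifts the covariate fit recovered 31% of genes changed by 0.5 and 91% of those changed by 1, while the season fit on data without shifts recovered 53% and 99%. CHG and CHH sites were not tested, since libraries listed 19 to 313 CHG and 5 to 66 CHH cytosines.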

Results

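The series holds 60 bisulfite libraries of vegetative buds from Norway spruce of genotype B10V. Each library was made from several terminal buds and enriched for 2738 gene targets. The labels give a treatment of 18 or 28 without a unit, taken here as the temperature in degrees Celsius during embryogenesis. Buds were collected on 10 dates from 18 February to 19 December, with 3 libraries per treatment and date. The titles repeat 6 numbers over the dates. In ascending order within each treatment they are called A, B and C at 18 degrees and D, E and F at 28 degrees. The 59 usable libraries held between 3731291 and 38123091 methylated and unmethylated calls at CG sites, with a median of 18 to 80 reads per listed cytosine. The 28 degree library of number E from 6 May listed 38 cytosines and was left out. A total of 180018 CG sites had at least 10 reads in at least 80% of the usable libraries.

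Spruce CG sites were mostly either bare or fully methylated. Of the common sites, 74.1% had a level under 5% and 14.6% had a level over 75%. The unweighted mean level was highest, at 59.5 ± 1.28% (SD over 59 libraries), from -1800 to -1701 bp of the annotated gene start. It was lowest, at 7.03 ± 0.57%, from -200 to -101 bp. In the captured gene part it stayed near 10.5 ± 0.875%. The gene sequence began with ATG in 2162 of 2214 annotated targets, so positions count mostly from a start codon and not from a known transcription start. The median gene of the 2733 tested had a level of 10.03%, and 16.8% of genes had a level over 50%.

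**Figure D1:**
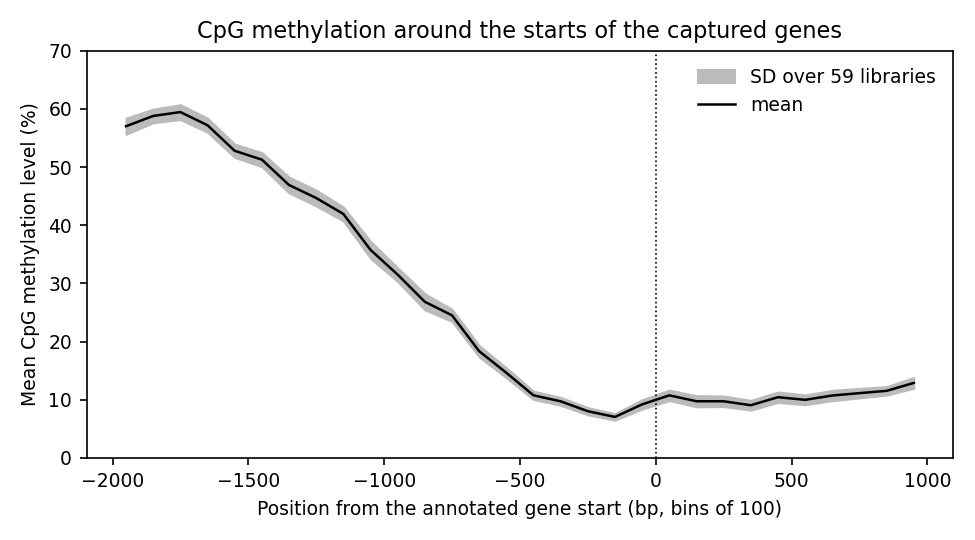
The line gives the mean CpG methylation level in percent (y axis) against the position from the annotated gene start in bp (x axis, bins of 100), and the band gives the SD over 59 libraries. The level was 59.5% in its highest bin and 7.03% in its lowest, just upstream of the start.

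Gene groups differed in how methylated they were. The 71 genes of histone modification and chromatin averaged 38.2 ± 33.7% (SD over genes), against 22.6% for all 2114 annotated and tested genes (two-sided permutation test, p = 1e-05, the smallest the resamples can give, BH-adjusted p = 0.00012 over 12 lists). The 5 genes of the DNA methylation list averaged 43.5 ± 39.1% (p = 0.0653 by permutation, adjusted 0.196). At the other end, 8 cell wall genes averaged 2.18 ± 1.77% (permutation p = 0.0290, adjusted 0.163) and 17 defence genes averaged 9.20 ± 10.2% (p = 0.0406, adjusted 0.163), neither of which passed the adjustment. Heat shock and chaperone genes (27 genes, 14.3%), auxin genes (11 genes, 10.6%), cytokinin genes (6 genes, 10.4%), ethylene genes (5 genes, 15.3%), cell cycle genes (65 genes, 19.0%), transposon-related genes (8 genes, 19.0%), cold and dehydration genes (9 genes, 20.3%) and ribosomal protein genes (32 genes, 21.6%) did not pass either, each with an adjusted p of 0.270 or more. The lists were built from domain descriptions, so several members do not do what a list says. The cell cycle list holds tetratricopeptide repeat, pentatricopeptide repeat and RING finger genes through anaphase-promoting-complex hits, and the cytokinin list holds HSP90 chaperones through their ATPase domain.

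The annotation also gives the reason why the authors chose a gene. The 103 genes of interest marked as differentially expressed averaged 50.7 ± 36.5%, and the 203 marked as not differentially expressed averaged 39.1 ± 34.5%. The 1438 genes of the set called golden averaged 18.4 ± 23.0%. Each of these differed from all annotated genes (permutation p = 1e-05, the smallest possible, adjusted 3e-05 over 9 reasons). Among the other reasons, genes higher in leaf primordia at 18 averaged 16.1 ± 23.0% over 72 genes, which did not pass (permutation p = 0.0391, adjusted 0.0880).

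Whether the temperature of embryogenesis left a difference in the buds was asked first for the level over all sites. The pooled CpG level, which weights sites by their reads, was 24.3 ± 0.969% at 18 degrees and 23.5 ± 1.30% at 28 degrees (mean ± SD of 3 numbers each). The difference of -0.812 points was within the spread between numbers (two-sided exact permutation test, p = 0.4 of 20 assignments, smallest possible 0.1), and it was -0.372 points without the 28 degree library E of 5 November. At single dates the 3 largest gaps went down at 28 degrees. On 18 June the level was 29.3 ± 3.03% at 18 and 23.7 ± 1.38% at 28, and on 19 December it was 22.2 ± 2.43% and 18.2 ± 0.62% (n = 3 each, exact p = 0.1 in both, the smallest that 3 against 3 allows, adjusted 0.5). On 5 November it was 25.04 ± 1.93% and 20.6 ± 6.6% (exact p = 0.5), and the gap of -4.46 points was -0.69 without that library. On 5 June and 13 June the 28 degree mean was the higher, by 3.41 and 3.29 points, with an exact p of 0.4 and 0.3. The gap of 5 June was 6.01 points without 1 of its A libraries and 1.77 without C, and that of 13 June was 1.90 without D.

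A pseudo-response regulator gene carried the clearest temperature difference of any gene. MA_71728g0010 encodes a response regulator receiver domain with a CCT motif, the domain pair of the clock's pseudo-response regulators. Its level was 1.80 ± 0.0689% at 18 degrees and 0.274 ± 0.0575% at 28 degrees (SD, n = 3 numbers; log2 odds ratio -2.75, edgeR quasi-likelihood FDR 0.00395). It was the only 1 of 2733 genes past FDR 0.05, and 239 genes had an unadjusted p under 0.05. The difference rested on a single CG pair at positions 3013 and 3014 of its target, base 513 from the gene start in GATTTTCCTCCGACAATGAAAT. The 3 numbers at 18 degrees averaged 48.3 ± 8.87% there and the 3 at 28 averaged 0.70 ± 0.66%. Another site of the gene, at position 2393, was raised in number B alone, with 32.4% against at most 2.19% in the other numbers. Among 26 libraries at 18 degrees the median was 51.7% (20.8 to 71.2%), and among 28 libraries at 28 degrees it was 0%, with 4.88% as the highest. The 18 degree libraries of number B from 20 March and 6 May did not follow the others, with 1 of 64 and 0 of 49 reads methylated. At a coverage minimum of 20 the pair was lost and the gene no longer passed (log2 odds ratio -0.64, FDR 0.577), and without number D its FDR was 0.0524. Over all alternatives its FDR ranged from 3.75e-11 to 0.577.

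**Figure D2:**
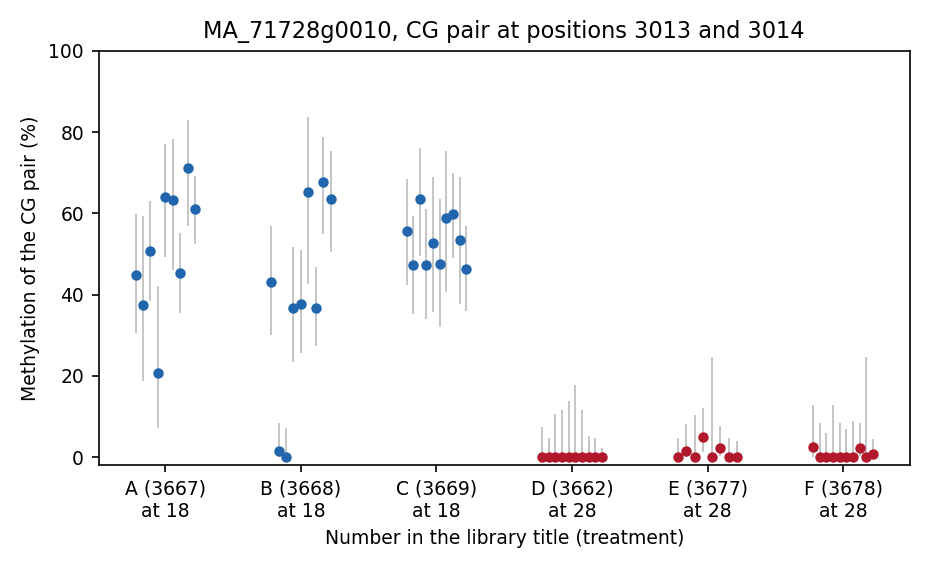
Points give the methylation in percent (y axis) of the CG pair in MA_71728g0010 in each library, grouped by the number in its title (x axis), with exact 95% binomial intervals that cover counting error only. The 18 degree libraries lay between 20.8 and 71.2% except the pair from number B near 0, and no 28 degree library was above 4.88%.

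None of the gene lists held a temperature call over all genes, by edgeR or by limma. MA_71728g0010 itself was in none of them, so the photoreceptor and clock list missed a gene with the clock regulators' domain pair. Adjusted over the list alone, 1 gene passed in the cell wall list and 0 in each of the others. That gene, MA_254951g0010, has xyloglucan endotransglycosylase domains, of the enzymes that loosen and rejoin cell wall xyloglucan, and was named after its values were seen. It had a level of 1.19 ± 0.0510% at 18 and 0.864 ± 0.0341% at 28 degrees (log2 odds ratio -0.46, edgeR FDR over all genes 0.556). The other xyloglucan and pectinesterase genes of the list did not pass. In 489 genes (17.9%) the 3 numbers of 18 degrees did not overlap those of 28, where chance gives 10% for a single gene. Genes share the sums of the same numbers, so a shift of a whole number moves many genes together. The share was not counted for other splits of the numbers, so its distance from 10% cannot be tied to temperature. Splitting single cytosines by temperature gave 0 calls of 105089 sites by edgeR, with 4632 sites (4.41%) at an unadjusted p under 0.05. By limma it gave 19 calls (9 higher and 10 lower at 28). At 11228 sites (10.7%) the numbers did not overlap, where chance gives 10% for a single site, and the same limit holds.

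At single dates, 35 gene and date pairs passed (16 higher and 19 lower at 28 degrees, edgeR, FDR within each date). MA_71728g0010 was lower at 28 on 19 December, with 2.67 ± 0.67% at 18 and 0.09 ± 0.06% at 28 (n = 3 each, log2 odds ratio -4.84, FDR 0.000108). MA_10435431g0020, which carries a CCT motif alone, was lower on 5 June, with 2.09 ± 0.36% and 0.20 ± 0.14% (-3.54, FDR 0.00642). On the same date the pentatricopeptide repeat gene MA_774352g0010 was higher at 28, with 0.30 ± 0.34% and 12.7 ± 1.26% (5.25, FDR 0.00102), a direction that turned at a coverage minimum of 20. The repeat gene MA_59599g0010 was lower on 5 November, with 42.0 ± 10.6% and 21.8 ± 5.66% (-1.39, FDR 0.00938). The DYW gene MA_3449g0010 was lower on 19 December, with 30.6 ± 3.62% and 16.4 ± 6.65% (-1.24, FDR 0.0101). The calls fell on 5 June (15, of which 14 higher), 5 November (16, of which 14 lower) and 19 December (4, all lower), and the other 7 dates had 0 by edgeR with 15 to 324 genes at an unadjusted p under 0.05. With treatments shuffled within dates, the same dates drew up to 41, 76 and 37 calls, so the calls cannot be tied to temperature on these dates. The fit used 1 spread for all groups, while the SD of the pooled level at 28 degrees was 6.6 points on 5 November and 0.16 on 18 September. Without the 28 degree library E of 5 November, 5 November had 0 calls by edgeR (245 genes at an unadjusted p under 0.05), 19 December 155 and 5 June 27, and MA_59599g0010 no longer passed (log2 odds ratio -1.11, FDR 0.127). Leaving out each number in turn, MA_71728g0010 passed each time. The FDR of MA_59599g0010 was 0.132 without A, 0.0519 without B and 0.161 without E (log2 odds ratio -1.74 to -1.10 over the numbers left out). That of MA_3449g0010 was 0.13 without B, 0.135 without C and 0.1 without E (-1.59 to -0.86). On 5 June no title holds B or E, and without A or D a treatment keeps a single library. For that date MA_774352g0010 ranged from 4.39 to 6.86 over the numbers left out. MA_10435431g0020 ranged from -4.09 to -3.34, with an FDR of 0.0534 without F. With the coverage ratio in the fit each gene named here kept an FDR of 0.0237 or less. At a coverage minimum of 20 MA_59599g0010 passed and the others did not, with an FDR of 0.318 for MA_71728g0010, which also had 0.106 by limma on unweighted means. By that fit MA_3449g0010 had -0.02 (FDR 1) and MA_59599g0010 -0.34 (FDR 0.151), and MA_3449g0010 had -0.87 (FDR 0.129) by limma after centring. By limma 248 pairs passed over all dates (51 higher and 197 lower). With limma after centring of each library the split was 93 higher and 101 lower.

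The annual cycle was asked by setting November to March against June and July. The pooled CpG level was 21.97 ± 2.86% on the November to March dates and 26.7 ± 3.03% on the June and July dates (SD, 24 libraries each). It fell by 4.71 points (two-sided permutation test within temperatures, p = 1e-05, the smallest the resamples can give), by 3.74 points at 18 degrees and by 5.67 points at 28. The permutation tests of this comparison moved single libraries, and the edgeR season fit took its error from libraries of the same treatment and date. Season was set per date, so both treat the libraries of a date as independent, and their p-values may be too small. All 6 numbers were lower in November to March, by differences from -7.52 to -2.19 points (to -1.76 without 5 June and the B library of 20 March). As the pooled level weights sites by their reads, it also falls when methylated sites receive fewer reads. Counting each site once, the levels were 17.9 ± 0.858% and 19.1 ± 1.12% (-1.15 points, permutation p = 1e-05). Within the dates of the first index set the pooled difference was -4.03 points (permutation p = 0.0002). Adjusted for the coverage ratio of each library, the pooled difference was -1.07 points (permutation p = 2e-05) and the unweighted one 0.107 points (p = 0.453).

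**Figure D3:**
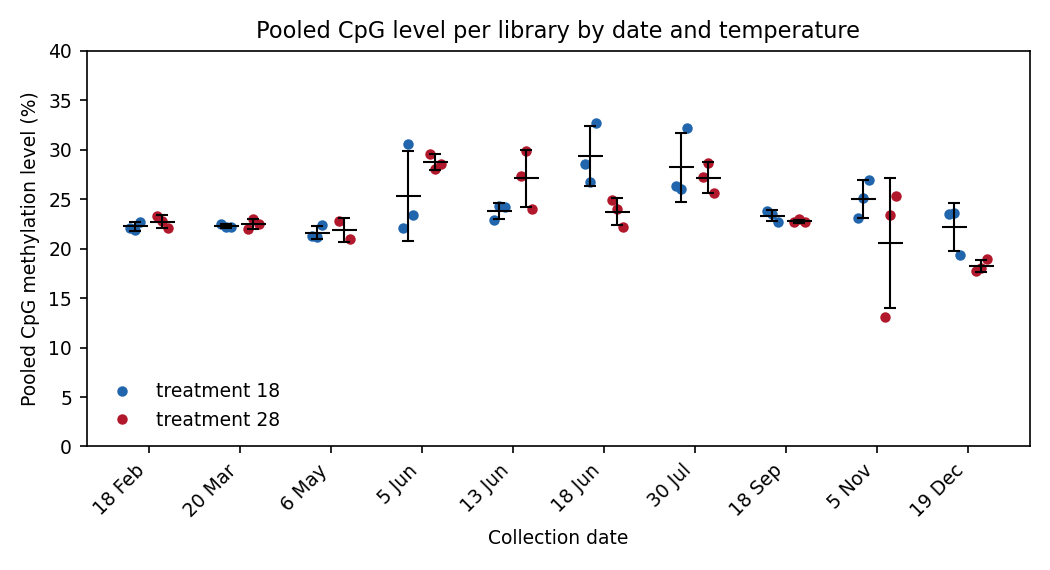
Points give the pooled CpG methylation level in percent (y axis) of each library by collection date (x axis) and treatment (color), with mean and SD of up to 3 libraries as bars. November to March dates averaged 21.97% and June and July dates 26.7%, and a 28 degree library of 5 November lay lowest at 13.0%.

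The genes that were lower in the cold season included a pathogenesis-related gene and a glycosyltransferase. MA_135328g0010, of the Bet v I family of pathogenesis-related proteins, had 29.6 ± 11.9% in November to March and 44.9 ± 6.92% in June and July (log2 odds ratio -1.18, edgeR FDR 4.17e-05; SD over 24 libraries each). The UDP-glucosyl transferase gene MA_10433477g0020 had 25 ± 8.84% and 39.0 ± 8.73% (-1.05, FDR 1.68e-05). MA_152693g0010 (23.6 and 35.9%), MA_10429924g0020 (55.1 and 67.1%) and MA_19301g0010 (17.3 and 29.1%), which carry no domain description, followed in the same direction. The SET domain gene MA_10435993g0020, of the family of lysine methyltransferases, went the other way, with 70.3 ± 8.07% in November to March and 61.9 ± 3.20% in June and July (0.61, FDR 5.45e-05). MA_10430646g0010 of the GDA1/CD39 nucleoside phosphatases (67.9 and 59.7%), the DYW deaminase gene MA_10432861g0020 (62.1 and 55.1%), MA_92795g0010 (43.5 and 36.1%) and MA_112985g0010 (59.7 and 55.4%) were also higher. Each of these 10 genes moved the same way in all 6 title numbers, and all but MA_92795g0010 did so without 5 June and the B library of 20 March, where private sites and titles did not match in 5 libraries. MA_135328g0010, MA_10433477g0020 and MA_10429924g0020 each turned in 1 of 20 alternatives, a centred one, and passed in the other direction there. None of the 10 kept an FDR under 0.05 when the coverage ratio of each library entered the fit.

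In all, 1005 of 2733 genes differed between the seasons, 958 lower and 47 higher in November to March, and 640 and 27 of them did so in all 6 title numbers (558 and 19 without 5 June and the B library of 20 March). The median log2 odds ratio of all genes was -0.22, and 75.9% of genes lay below 0. By limma, after each library was centred on its own median, the split was 560 higher and 157 lower, with a median of 0.11. The coverage ratio compares, in each library, the reads at sites above 90% with the reads at sites below 2% methylation. It averaged -0.10 ± 0.15 (log2, 24 libraries) in November to March and 0.11 ± 0.17 (24 libraries) in June and July. Across 59 libraries it followed the shift of sites at 30 to 70% (Pearson r = 0.896, Spearman rho = 0.946, permutation p = 1e-05 each, adjusted 1e-05 over 3 relations; r = 0.922 without the 2 farthest libraries). Within treatment and date groups r was 0.886, and it was 0.877 over 36 libraries of the first and 0.985 over 23 of the second index set. The ratio followed the pooled level more closely (r = 0.970, and 0.953 within groups), and the unweighted level with r = 0.899 (0.871 within groups). With this ratio in the fit 1 gene differed between the seasons by edgeR, MA_180673g0010 (log2 odds ratio -0.55, FDR 0.0193, and -0.74 without the ratio). With a replicate block and prefix numbers on 5 June as well, it did not pass either.

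**Figure D4:**
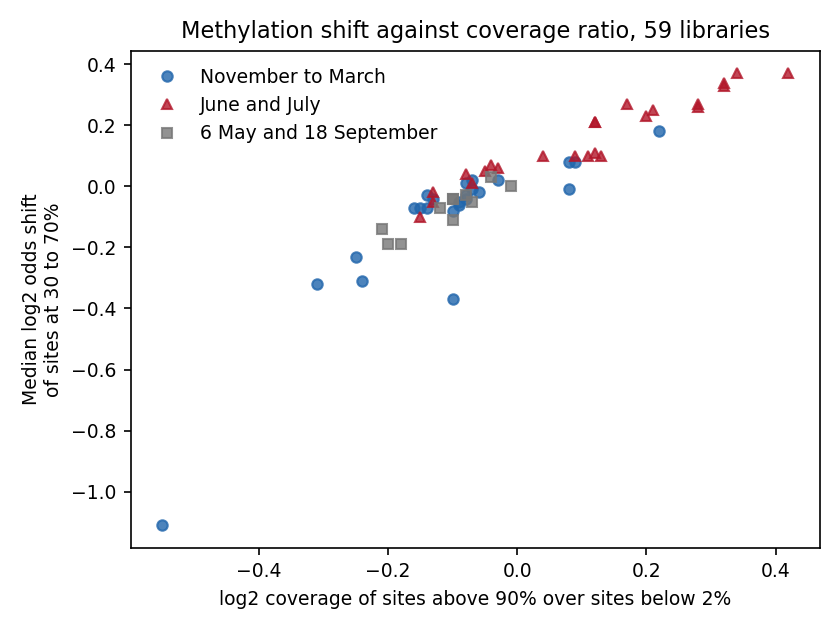
Each point is 1 of 59 libraries, with the log2 ratio of coverage at sites above 90% over sites below 2% methylation on the x axis and the median log2 odds shift of sites at 30 to 70% on the y axis. June and July libraries averaged 0.11 on the x axis and November to March libraries -0.10.

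Chromatin genes moved both ways with season. Of the 71 members 3 were higher and 21 lower in November to March (24 adjusted over the list alone), with the SET domain gene MA_10435993g0020 higher and MA_135627g0010, a Myb-like gene with a bromodomain, lower (16.5 ± 3.48% and 26.4 ± 8.87%, log2 odds ratio -0.83, edgeR FDR 1.68e-05). The DNA methylation list had 1 of 5 genes higher (0 adjusted over the list alone), MA_10430322g0010, a methylase-domain gene with other RNA and adenine methylase hits (0.25), which did not pass without the 28 degree library E of 5 November (0.21, FDR 0.0579). The auxin list had 1 higher and 2 lower of 11 (3 over the list alone). Its lower gene MA_2421g0010 has the B3 and AUX/IAA domains of an auxin response factor (-0.49), and its higher gene MA_10427420g0010 (0.18) has a Piwi domain, as argonautes do, and is no auxin gene by its domains. MA_135627g0010 and MA_2421g0010 passed in the other direction in 1 centred alternative.

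In the lists for cold, heat shock, abscisic acid, ethylene, cytokinin and defence, the genes that passed were lower in November to March. So were 95.3% of all genes that passed for season. Over all members, passed or not, the cold list had a median log2 odds ratio of 0.10, and the medians of the other lists named here were negative, as was that of all genes (-0.22). The 2 of 9 cold and dehydration genes (2 over the list alone) were the late embryogenesis abundant gene MA_487701g0010, with 11.9 ± 3.61% and 18.6 ± 7.90% (-0.74, edgeR FDR 0.00175), and the AP2 domain gene MA_10020434g0010 (-0.36). Heat shock and chaperone genes had 9 of 27 (9 over the list alone), led by the DnaJ genes MA_176222g0010 (-0.78) and MA_3706g0020 (-0.42). The 2 of 3 abscisic acid genes (2) were the ABA/WDS induced genes MA_10427828g0010 (-0.44) and MA_10429943g0030 (-0.34). The 2 of 5 ethylene genes (2) were the CTR1-like kinase gene MA_10437092g0010 (-0.33) and the kinase gene MA_10194g0020 (-0.51). The 3 of 6 cytokinin members (3) were the HSP90 genes MA_82160g0010 (-0.29) and MA_10434030g0010 (-0.44), and the glycosyl transferase gene MA_10426467g0020 (-0.48), none of which acts in cytokinin signalling by its domains. None of 3 gibberellin genes passed (edgeR, 0 over the list alone). Adjusted over the list alone, 10 of 17 defence genes passed, and 9 over all genes, among them the Bet v I gene MA_135328g0010 and the class I chitinase gene MA_10425967g0010, with 14.1 ± 3.76% and 19.4 ± 5.28% (-0.57, FDR 0.000629). Of the genes named in these lists, MA_3706g0020 and MA_10194g0020 kept their direction under every alternative run, and each of the others turned in at least 1. With the coverage ratio in the fit none of the genes named in these lists passed by edgeR. MA_3706g0020 was then -0.02 (FDR 0.977), MA_10194g0020 -0.16 (0.736), MA_10020434g0010 -0.03 (0.967), MA_10429943g0030 -0.02 (0.979) and MA_10434030g0010 0.00 (0.999). MA_176222g0010, MA_82160g0010 and MA_10425967g0010 turned in that fit (0.09, 0.04 and 0.03). MA_487701g0010, MA_10427828g0010, MA_10437092g0010 and MA_10425967g0010 passed in the other direction in a centred alternative.

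Clock, flowering and wall genes gave short lists. The SRR1 gene MA_1038617g0010, named for a regulator of phytochrome B signalling and the clock, was lower (39.4 ± 8.31% and 48.2 ± 8.10%, -0.54, edgeR FDR 0.00119), as 1 of 3 photoreceptor and clock genes (1 over the list alone). The single flowering list member, MA_221964g0010, was lower (-0.30, 1 over the list alone). It has a Floricaula/Leafy domain hit beside a Rab-GTPase-TBC domain, so its place in the list is uncertain. Of 8 cell wall genes 5 were lower (5 over the list alone), such as the pectinesterase gene MA_177306g0010 (2.69 ± 1.14% and 4.41 ± 1.44%, -0.86, FDR 0.000346) and the xyloglucan endotransglycosylase gene MA_10430703g0010 (-0.45). Cell cycle genes had 1 higher and 27 lower of 65 (28 over the list alone), with the repeat genes MA_112066g0010 (-0.75) and MA_9641858g0010 (-0.62) in front. Ribosomal protein genes had 1 higher and 10 lower of 32 (12 over the list alone), with the repeat genes MA_10432217g0030 (-0.51) and MA_953506g0010 (-0.56) in front. Transposon-related genes had 4 lower of 8 (4), among them MA_455618g0010 (-0.34) and the receptor kinase-like gene MA_10429487g0020 (-0.68). MA_455618g0010 has a reverse transcriptase and a type II intron maturase domain, so it need not be a transposon gene. It did not pass without the 28 degree library E of 5 November (FDR 0.0685). MA_1038617g0010, MA_177306g0010, MA_10430703g0010 and MA_112066g0010 kept their direction under every alternative run, but with the coverage ratio in the fit they were -0.19 (FDR 0.765), -0.24 (0.752), -0.02 (0.979) and -0.13 (0.862). MA_9641858g0010, MA_10432217g0030, MA_953506g0010 and MA_455618g0010 passed in the other direction in a centred one, and MA_221964g0010 and MA_10429487g0020 turned without passing. Of the 36 season genes named by the rule or from the lists, 15 kept their direction under every alternative run, and none passed with the coverage ratio in the fit. No list had a share of calls that differed past the threshold from the 37.1% of all 2114 annotated genes (two-sided Fisher's exact tests, adjusted p of 0.977 or more). The small RNA list had 0 members, as its terms missed the Piwi domain of MA_10427420g0010, which was counted in the auxin list.

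Between any of the 10 dates, the strongest gene was a fully methylated one. MA_3430g0010, without a domain description, had 90.9 ± 0.980% on 6 May (n = 5 libraries) and 92.6 to 93.5% on the other dates (n = 6 each, edgeR F test, FDR 4.93e-06). The 6 May libraries were lower over all sites above 90% as well, with 94.98 ± 0.54% (n = 5) against 96.3 ± 0.191% on the other dates (n = 54). MA_180673g0010, with a DUF1767 domain, ranged from 8.97 ± 3.99% on 19 December to 20.6 ± 4.90% on 5 June (FDR 8.70e-06). MA_5288g0010 ranged from 0.860 ± 0.36% on 19 December to 4.38 ± 2.18% on 30 July (FDR 8.83e-06). In all 482 genes passed, of which 407 also differed between the seasons. The count was 880 without the 28 degree library E of 5 November, 130 with the coverage ratio in the fit, 21 in the first index set and 60 without number A. Members past FDR 0.05 numbered 13 for chromatin, 9 for cell cycle, 4 for defence, 3 for ribosomal proteins, 2 each for auxin, cold, heat shock and cell wall, 1 each for photoreceptors and clock, cytokinin and ethylene, and 0 for the rest of the lists. Adjusted over the list alone the counts were the same except 2 for photoreceptors and clock, 3 for cold, 1 for heat shock, 3 for abscisic acid and 1 for gibberellin.

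Whether the seasonal difference itself differed between the temperatures was tested by an interaction term. No gene passed by edgeR (smallest FDR 0.229, 201 of 2733 genes at an unadjusted p under 0.05) or by limma, and every list had 0, also adjusted over the list alone. The 3 smallest p belonged to the glycosyl transferase family 2 gene MA_10432931g0010 (log2 odds ratio -0.84), the WD repeat gene MA_29512g0010 (-0.80) and the DYW gene MA_9258g0010 (-0.66), and none of these passed.

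Libraries of the 6 numbers were told apart by private sites, cytosines at which 1 of the 6 numbers stood at least 30 points from all the others. There were 880 such sites in 565 genes, 589 higher and 291 lower, with a median difference of 45.8 points. On dates left out of their choice 760 of them (86.4%) kept at least 20 points in the same direction. With the numbers shuffled 20 times a median of 119 sites and at most 173 were found. The largest group lay in MA_88982g0010, where 10 sites from positions 2586 to 2721 were higher in number A. Outside 5 June 51 of 53 libraries matched the number in their title, with scores of at least 0.770. The 18 degree libraries of number B from 20 March and 6 May matched none of the 6 numbers, and on 5 June 4 of 6 libraries matched another number than that of their title.

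**Figure D5:**
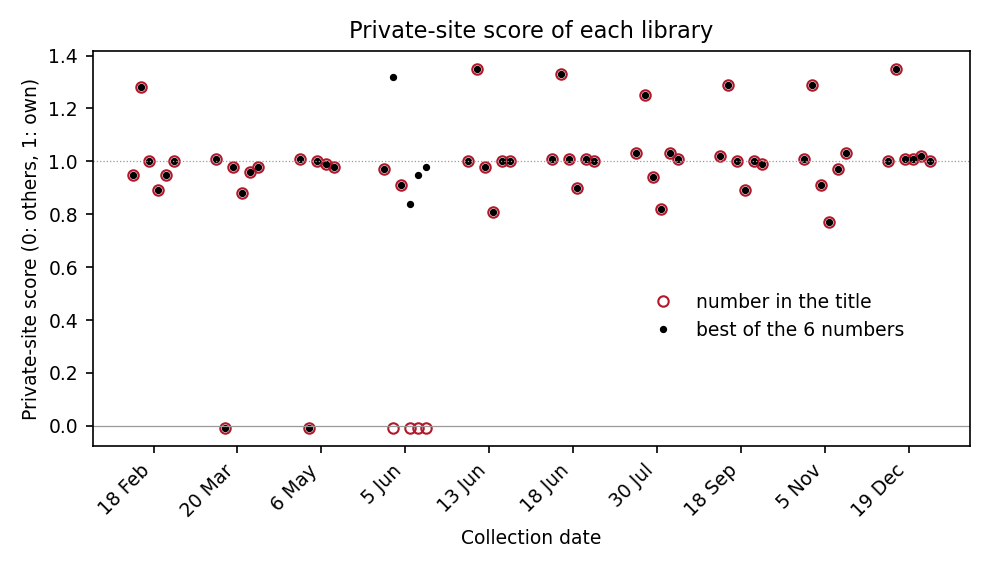
For each of 59 libraries by collection date (x axis), the y axis gives the private-site score, where 0 is the level of the other numbers and 1 that of the number itself, for the number in the title (circles) and for the best of the 6 numbers (dots). On 5 June 4 circles lie near 0 below their dots, and on 20 March and 6 May 1 library each scores near 0 for every number.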

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

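The splits of samples and the tests with the coverage ratio, private sites and parting sites were chosen after the results were seen, while the comparison within the first index set was planned.

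The 28 degree library of number E from 5 November lay far below its date. Its pooled CpG level was 13.0%, against 23.1 to 27.0% in the other 5 libraries. Its unweighted mean was 14.3%, against 18.1 to 19.3% on that date and 17.2 to 19.5% in the other libraries of number E. The 18 degree library of number A lay above its date on 18 June (21.0%, others 18.0 to 19.1%) and on 30 July (22.3%, others 18.6 to 19.7%). Chance sets apart a sample in about 1 of 20 sets, and 5 of 32 sets formed had one. The sets of numbers A and D held too many libraries for the limits used. The 5 include the E library of 5 November more than once, so they are not independent.

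On 20 March the unweighted mean was higher in every 28 degree library than in every 18 degree library, by 0.169 points, and on 18 June it was lower in every one, by a difference of -1.31 points. The difference between these dates was not tested. Outside the main measurement, the listed CHG cytosines had a pooled level of 17.5% (18886 of 108220 reads) and CHH cytosines 5.80% (1882 of 32457 reads). The near-empty 28 degree library of 6 May had 301 of 530 CG reads methylated, 56.8% (Wilson 95% interval 52.5 to 60.9%).

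The CpG level was lower in November to March than in June and July. The tables argue against the index sets as the whole cause, since the difference within the first set was -4.03 points. Within that set the June libraries reuse the index reads of the November to March libraries, so they could not share a pool. The comparison therefore cannot tell season from a difference between pools. Unequal recovery of methylated and unmethylated molecules between libraries remains a candidate explanation, because with the coverage ratio as covariate 1 gene differed by season. That fit recovered 91% of simulated changes of 1 (log2) and 31% of those of 0.5, so smaller seasonal changes could be missed. A seasonal change in the buds stays open, as the adjusted pooled difference was -1.07 points (permutation p = 2e-05) and the adjusted unweighted one 0.107 points (p = 0.453). When single libraries were shuffled over the dates, the highest of 39 other draws called 1 gene for season, against 1005. For dates the highest called 250, against 482, a draw that points to a structure of the samples. Chance assignment of single libraries could thus be excluded. The draws break up the libraries of a date, so they cannot exclude shifts shared by a date. Simulated libraries with the measured shifts and no gene changed gave 275 season calls.

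Some libraries carried private sites of another number than their title says. On 5 June the labels may carry exchanged numbers, since the 5 libraries whose prefix has a single number on other dates all matched it (permutation p = 0.00139, the smallest of 720 orders). The sixth has a prefix that went with B and C on other dates, and it matched C, its title number. For the 18 degree B libraries of 20 March and 6 May the tables argue against a mixture of the 6 numbers, as the highest score of the first was -0.00646. A further plant is a candidate source, since 77.2% of the sites that set the March library apart repeated in the May library. No biological explanation was tested.

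At 12 sites the 3 numbers at 18 degrees were parted from the 3 at 28 by at least 30 points. Differences between single plants unrelated to temperature may give as many, since 5 other splits of the 6 numbers parted 12 sites or more, with 23 as the highest. Temperature during embryogenesis stays open for the CG pair of MA_71728g0010, because the odd B library of 20 March had 1.56% there and its plant of origin is unknown. The 10 splits are too few for a share under 0.05, with 1 gene in the real split and 2 in the highest other, and 3 of the 10 gave as many. At an unadjusted p under 0.05 the real split had 239 genes against 179 in the highest other, and 4632 sites against 4435. For sites edgeR called 0 in each of the 10 splits, so that count decides nothing, and limma called 19 in the real split and 20 in the highest other.

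At single dates chance could not be excluded. The real assignment called 35 gene and date pairs, and the highest of 20 other draws within dates called 100 (9 of 21 draws as many). For the interaction it called 0 by edgeR, with 201 genes at an unadjusted p under 0.05 and 0 by limma, and the highest other draw called 95. Since each of the 21 draws reaches a count of 0, this decides nothing about chance. Draws with several times the real count point to a structure of the samples.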

How the results depend on the processing

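Alternatives with the coverage ratio, with numbers taken from the prefix, with sites covered in every library, without single libraries, or at single dates without a number were chosen after seeing the data, and the others were planned. The cause was not tested for any change below unless stated.

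For temperature 1 gene passed, and 0 passed at a minimum of 5 points, on sites covered in every library and at a coverage minimum of 20, which dropped the CG pair of MA_71728g0010 (edgeR, 196 and 231 genes at an unadjusted p under 0.05). All libraries as replicates gave 35 genes and a block by estimated correlation gave 27. Leaving out each number gave 0 (without D, 318 at an unadjusted p under 0.05) to 3 (without C), with 2 without B. Single sites gave 19 by limma and 0 to 0 without each number. The overall temperature difference ranged from -1.51 to -0.226 points without each number and was -0.372 without the 28 degree library E of 5 November. Without each number MA_71728g0010 ranged from -2.88 to -2.59 and MA_254951g0010 from -0.48 to -0.43. At a coverage minimum of 20 the first was -0.64, and by limma on unweighted means they were -2.08 and -0.21.

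For season 1005 genes passed. The count was 308 at 5 points, 524 on sites covered in every library, 273 in the first index set, 464 by limma on unweighted means, 486 (318 higher) with these centred and fitted with block and prefix numbers on 5 June, 577 for sums per number and season, and 560 without 19 December and the 28 degree library E of 5 November. With the coverage ratio it was 1, with block and prefix numbers as well 0 (edgeR, 218 genes at an unadjusted p under 0.05), and 12 without the 5 November library. Leaving out each number gave 434 (without A) to 1034. The overall difference ranged from -5.43 to -3.79 points without each number. It was -5.50 at a coverage minimum of 20, -1.15 for the unweighted mean, -0.704 for that over sites covered in every library and -1.07 adjusted for the coverage ratio, and turned only for the unweighted mean adjusted for the coverage ratio, at 0.107. The replicate block, a hint from the data, gave 988 genes. The titles repeat the numbers over the dates, and in the pairing check residuals correlated at 0.108 within and -0.054 between numbers, with 144 of 262 same-number pairs above 0.1.

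For dates 482 genes passed, with 257 for centred unweighted means over sites covered in every library with block and prefix numbers, 229 on such sites, 291 at a coverage minimum of 20, 21 in the first index set, 157 for unweighted means, 123 with these centred and fitted with block and prefix numbers, and 880 without the 5 November library. With the coverage ratio it was 130, with block and prefix numbers as well 153 and without the 5 November library 172. Leaving out each number gave 60 (without A) to 523, with 114 without D, 183 without B and 273 without C. The interaction stayed at 0 in 19 settings (edgeR and limma, 201 genes at an unadjusted p under 0.05 in edgeR) and at 0 to 2 without each number.

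At single dates 35 pairs passed, with 15 at a coverage minimum of 20, 194 by limma after centring, 248 by limma, 130 by unweighted means, 23 without the odd B libraries of 20 March and 6 May, 56 without 5 June, 182 without the 5 November library, 17 with the coverage ratio and 62 with it and without that library. Leaving out each number gave 6 (without B) to 429 (without F), with 307 without D. MA_774352g0010 turned to -0.31 at a coverage minimum of 20.

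Over 36 season genes and 716 settings, 430 values kept direction and side of the threshold, 238 kept direction only and 48 turned. After centring, with or without block and prefix numbers, MA_221964g0010 (0.038), MA_82160g0010 (0.051), MA_10437092g0010 (0.009) and MA_455618g0010 (0.008) turned. At a coverage minimum of 20 MA_487701g0010 turned (0.453), as on sites covered in every library (0.641). With the coverage ratio MA_176222g0010 (0.093), MA_82160g0010 (0.037), MA_10429487g0020 (0.084) and MA_10425967g0010 (0.031) turned. With block and prefix numbers as well these were 0.199, 0.084, 0.137 and 0.072, and MA_10429943g0030 (0.005) and MA_10434030g0010 (0.073) turned. With the coverage ratio and without the 5 November library MA_221964g0010 (0.045), MA_82160g0010 (0.095), MA_10426467g0020 (0.089) and MA_455618g0010 (0.052) turned. By limma on unweighted means MA_10437092g0010 turned (0.15).

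With centred unweighted means, block and prefix numbers, MA_10020434g0010 (0.092), MA_10426467g0020 (0.069), MA_10437092g0010 (0.273), MA_9641858g0010 (0.029), MA_455618g0010 (0.07), MA_10432217g0030 (0.056) and MA_10425967g0010 (0.034) turned. On sites covered in every library such a fit turned MA_135328g0010 (0.143), MA_10433477g0020 (0.138), MA_10429924g0020 (0.084), MA_135627g0010 (0.114), MA_221964g0010 (0.023), MA_487701g0010 (0.351), MA_10020434g0010 (0.221), MA_176222g0010 (0.011), MA_10427828g0010 (0.136), MA_2421g0010 (0.197), MA_10426467g0020 (0.131), MA_9641858g0010 (0.141), MA_455618g0010 (0.135), MA_10432217g0030 (0.165), MA_953506g0010 (0.143) and MA_10425967g0010 (0.105), and the interaction values of MA_29512g0010 (0.011) and MA_9258g0010 (0.104).

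A coverage minimum of 5 was not run, since no listed cytosine has under 10 reads. CHG and CHH were not fitted. Depth limited the sites that entered, as a minimum of 20 reads left 109411 of 180018 common sites. The simulations did not vary depth or the noise from gene to gene.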

Other observations

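The tests of families and private sites were chosen after the values were seen, while the date test of MA_128457g0010 was planned and only the gene was picked afterwards.

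Protein families differed in methylation. Among 43 Pfam families of at least 20 genes, the 20 ubiquitin-conjugating enzyme genes averaged 47.6 ± 33.5% (SD over genes) and the 41 PHD-finger genes 41.5 ± 38.5%, against 22.3% for 1699 genes with a domain (permutation p = 0.00012 and 3e-05, adjusted 0.00215 and 0.00129). Tetratricopeptide repeat genes (PF13428, 108 genes) averaged 12.6 ± 12.9% (adjusted 0.00215), DYW deaminase genes (54) 11.8 ± 11.8% (0.0223) and Myb-like genes (PF00249, 26 genes) 8.68 ± 15.3% (0.0309). Other entries of these names went both ways: PF13176 passed (0.0292), and PF07719 (0.0910) and the Myb-like PF13921 (0.119) did not. Of the PF13428 genes 56 (51.9%) differed by season, against 36.5% of genes with a domain (two-sided Fisher's exact test, p = 0.00088, adjusted 0.0378). No other family passed for season, with tetratricopeptide entries PF13431 at an adjusted 0.0707 and PF13432 at 0.0714. The 56 calls are part of the 1005 season genes, of which 1 was left with the coverage ratio as covariate.

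MA_128457g0010, which has no domain description, had 41.6 ± 10.2% on 30 July (n = 6 libraries) and 10.4 to 24.3% on the other dates (edgeR FDR 8.83e-06 for dates). Over the alternatives its FDR ranged from 7.24e-07 to 1 (limma on unweighted means).

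Private sites lay upstream of the gene start in 63.1% of cases, against 51.9% of all placed sites. The partner cytosine on the other strand was private too in 65.9% of 352 pairs measured, and 13.3% of private sites had another within 100 bp.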
